A study of Homo sapiens with 8 samples.

How the data were processed

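The series measured RNA of ARPE-19 cells, an established human retinal pigment epithelial cell line, by RNA sequencing in 8 libraries. Per the labels, the cells were between passages 24 and 30, RNA was taken at 24 h after infection or treatment, and 4 groups of 2 libraries exist, named here mock, HCMV (human cytomegalovirus), untreated and zeocin. Mock and HCMV form 1 experiment and untreated and zeocin another, per the labels, so each treatment has control libraries of its own. The labels state 2 replicates per sample and do not say whether these were separate cultures. The p-values of single genes below therefore measure the spread between these libraries, which may be technical. Those of the gene lists compare genes with genes, under a preset or an estimated correlation between them, and those of Fisher's test count genes.

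Per the labels' protocols, RNA was harvested with Trizol and 1 ug of total RNA went into a TruSeq RNA library kit, with the same wording for all 8 libraries. Whether the libraries kept the strand of the RNA is not stated there, so reads of a gene and of an antisense partner cannot be told apart. STAR, featureCounts, Subread and DESeq2 are named in the submitters' processing notes, without versions or settings. The genome build, the annotation release and the viral strain's annotation are not given in the sources used here, and no coordinates are printed for this reason. The authors deposited 1 table of raw read counts per library, with no normalization: each holds 60725 rows of human gene identifiers and 167 rows of viral genes, and the values are whole numbers. The rows are the same in all 8 tables. Gene symbols and types came from a table of Ensembl names and from GENCODE release 29, which gave a symbol to 57055 of the human rows.

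Total counts per library ran from 9167702 (HCMV replicate 1) to 35913630 (mock replicate 1). Shares of a library's counts are given with exact 95% binomial intervals (Clopper-Pearson), and a count of 0 is given with the share that 3 counts would make. Both cover counting error only, since reads copied by PCR are not independent molecules. No pair of replicates was the same library: the chi-square of their counts over genes, divided by its degrees of freedom, was 90.6 for mock, 33.4 for HCMV, 18.2 for untreated and 20.0 for zeocin, where sampling noise alone gives 1.

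The human counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, two-sided), after its expression filter, which kept 21258 genes, and with TMM scaling. All 8 libraries and 4 groups entered a single fit, which shares its estimate of the spread and leaves 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are the log2 fold change divided by the square root of the test's F value. Levels are CPM (counts scaled to library size) of TMM-scaled human libraries, as mean ± SD of 2 libraries. Viral genes are given as CPM of all counts and were not tested, since every library without virus held 0. The comparisons were HCMV minus mock, zeocin minus untreated, the first effect minus the second, and mock minus untreated, which compares the experiments and not a treatment.

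The 22 gene lists were fixed from textbook knowledge before the data were examined, as were the tests, the rule for named genes and most alternatives. Each list except the leukocyte markers, of which 2 genes were tested, was tested with camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists of a comparison. A member count "adjusted over the list alone" applies Benjamini-Hochberg within the list. Candidates were called genes with a symbol that the annotation did not mark as pseudogenes. They lay on the same side in both treated libraries against both controls, and had at least 5 CPM in the higher group. Among these the rule named, per comparison, the 10 largest rises and the 10 largest falls. For the difference of effects it named the 5 largest and the 5 smallest. It also named up to 4 called members of each list with the smallest p, or the 2 most abundant where none was called, and always CDKN1A, MDM2, ATM, CHEK1 and CHEK2, and 1 further gene that is not reported here. For HCMV, where edgeR called no gene, the rule was also applied to the calls of DESeq2 1.42.0, a choice made after the counts of calls were seen.

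Alternatives were DESeq2, RLE scaling (relative log expression), library size alone, no filter on low counts, a stricter filter of at least 50 counts in 2 libraries, fits of each experiment alone, a replicate block, leaving out each library in turn, and a minimum absolute log2 fold change of 1. Others were added after the counts of calls were seen, namely limma voom with library weights, human and viral rows fitted together, and DESeq2 on each experiment alone. DESeq2 adjusted p-values given as NA were kept as NA. Mock and HCMV, and likewise untreated and zeocin, share replicate numbers, but with 2 numbers per experiment and no label that ties a number to a day or culture, the numbers were not taken as pairs.

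The tests were also run on simulated data, drawn from the real means and library sizes with 200 genes changed by known amounts and a list of 25 genes shifted together. For HCMV minus mock, over 19936 simulated genes, edgeR recovered 17% of genes changed by a log2 fold change of 1 and 86% of those changed by 2, and 9 of its 120 calls were false. DESeq2 recovered 31% and 87%, and 29 of its 160 calls were false. For zeocin minus untreated, over 19971 simulated genes, edgeR recovered 17% and 82% with 5 false calls of 108, and DESeq2 recovered 33% and 87% with 10 false calls of 138. For edgeR a recovered gene had to be called in the right direction, and a changed gene lost to the filter counted as missed. For DESeq2 the direction was not checked and filtered genes were left out, so the recovered percentages are not the same measure. Reads of near-identical gene copies, such as histone genes and 7SK copies, and of overlapping genes, common in the viral genome, could be split or lost by the authors' counting, and those values are uncertain. Repeat-derived RNA without a gene row was not analysed here.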

Results

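RNA of ARPE-19 cells, a human retinal pigment epithelial line, was sequenced 24 h after infection with human cytomegalovirus (HCMV), a herpesvirus that infects epithelial cells, or treatment with zeocin, a bleomycin-type drug that breaks DNA. Each condition had 2 libraries and 2 libraries of a control of its own, mock-infected or untreated cells. The mock libraries held 35913630 and 20923672 counts and the HCMV libraries 9167702 and 34524331. The untreated libraries held 24393734 and 21167513 counts and the zeocin libraries 24875912 and 24237769. HCMV replicate 1 was thus the shallowest. The comparisons ask which host genes change with infection, which change with drug-induced DNA damage, and whether the responses to the 2 treatments are alike. All values below rest on 2 libraries per group.

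Viral RNA was present in both HCMV libraries and in no other. Viral genes took 0.280% of the counts of HCMV replicate 1 (95% interval 0.277 to 0.284%) and 0.442% of replicate 2 (0.440 to 0.444%), a ratio of 1.58 that is larger than counting error. Each of the other 6 libraries held 0 viral counts, which allows at most 1.43e-05% in mock replicate 2, the shallowest of the 6. Of the 167 viral genes, 162 had counts in both HCMV libraries, 2 in a single one and 3 in none, and the order of the genes was alike in both libraries (Spearman correlation across viral genes 0.981). By counts, which were not corrected for gene length, the most abundant was UL54, the viral DNA polymerase, at 178.6 ± 67.1 CPM (counts scaled to library size, SD, n = 2). It was followed by UL132 at 139.7 ± 31.1 CPM and UL55, which encodes glycoprotein B, at 133.2 ± 19.3 CPM. The order of these differed between the libraries: UL55 was above UL132 in replicate 1 (4.26 against 4.20% of viral counts), and in replicate 2 it stood at 146.9 CPM, behind UL132 (161.7 CPM), UL112 (157.3 CPM) and UL148 (150.1 CPM). UL112 stood at 122.7 ± 49.0 CPM, UL44, the polymerase processivity factor, at 89.6 ± 32.8 CPM, and UL123, the immediate early protein IE1, at 67.4 CPM.

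**Figure D1:**
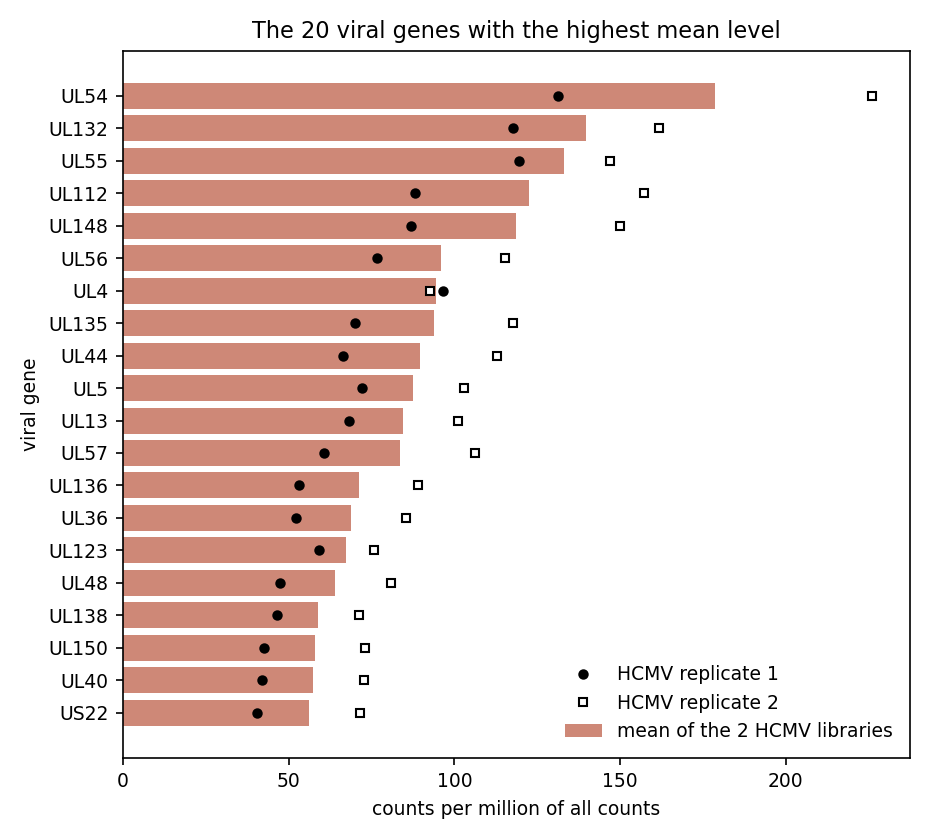
Level of the 20 most abundant viral genes in CPM of all counts (horizontal axis). Bars are the mean of the 2 HCMV libraries and points the single libraries. UL54 led with a mean of 178.6 CPM, and UL4 alone among the 20 was not higher in replicate 2.

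The libraries of the 2 experiments differed in the classes of RNA they held. SNORD3A, the U3 small nucleolar RNA, took 24.6 and 27.0% of the counts in the untreated libraries and 23.1 and 25.4% in the zeocin libraries, against 0.130 and 0.647% in the mock and 0.177 and 0.349% in the HCMV libraries. Mitochondrial ribosomal RNA took 11.4 to 14.6% in the zeocin experiment and at most 0.00867% in the infection experiment. In the other direction, ribosomal protein genes took 4.46 to 5.15% in the infection experiment and 0.840 to 0.887% in the zeocin experiment, and the 7SK RNA 1.29 to 1.86% against 0.177 to 0.195%. Mock minus untreated, which holds this gap between the experiments and no treatment, gave 8675 called genes (4725 higher and 3950 lower in mock, edgeR). Levels are therefore compared within an experiment, and the responses to the treatments through each one's own control.

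**Figure D2:**
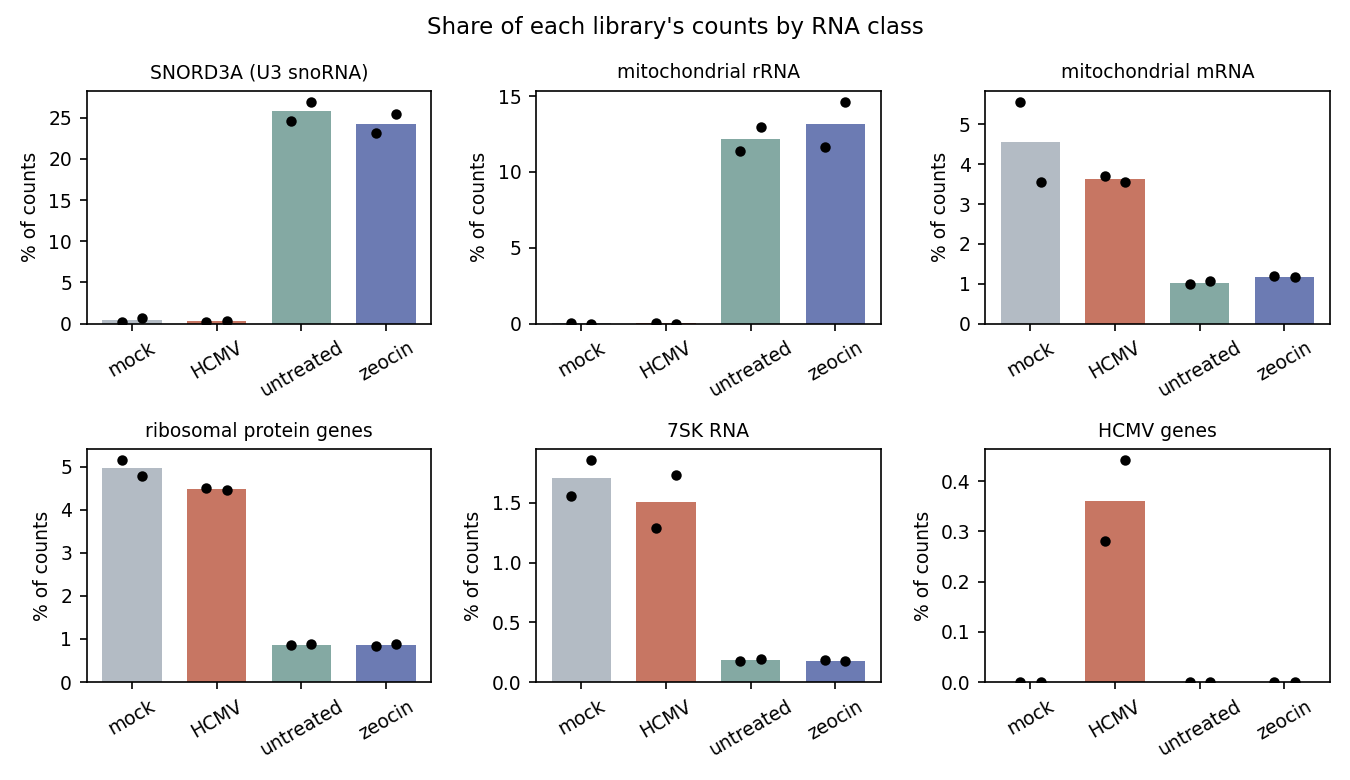
Percent of each library's counts (vertical axes, which differ in scale) in 6 classes of RNA, by group. Bars are group means and points single libraries. SNORD3A and mitochondrial rRNA are abundant only in the untreated and zeocin libraries, and viral counts occur only with HCMV.

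Zeocin lowered genes of cell division and raised other genes, p53 targets among them. Of 21258 genes tested, 218 were called, 89 higher and 129 lower, and 207 of them code for proteins. The split was 528 higher and 471 lower with DESeq2 on the experiment alone, 182 and 188 with voom weights, and 27 and 22 without untreated replicate 2. KIF20A, a mitotic kinesin, fell from 62.6 ± 4.1 to 9.0 ± 1.6 CPM (log2 fold change -2.79, SE 0.24, adjusted p = 0.000575), the smallest p of the comparison. PLAT, the tissue plasminogen activator, rose from 3.4 ± 1.1 to 40.4 ± 21.6 CPM (log2 fold change 3.59, SE 0.39, adjusted p = 0.00224). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 68.7 ± 8.7 to 178.0 ± 11.1 CPM (log2 fold change 1.37, SE 0.27, adjusted p = 0.0317).

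The list of mitosis genes moved furthest: 24 of its 30 members fell with zeocin, 29 when adjusted over the list alone, and none rose, with a median log2 fold change of -1.60. Beside KIF20A, CENPA, the centromeric histone H3, fell by 2.91 on the log2 scale (SE 0.33), NEK2, a centrosomal kinase, by 2.32 (SE 0.29), and MKI67, the proliferation marker Ki-67, by 2.27 (SE 0.27). The camera test placed the list below the other genes (adjusted p = 2.52e-51), a call lost at adjusted p = 0.0961 with an estimated correlation. Without zeocin replicate 1, 1 mitosis gene passed, and 8 passed without untreated replicate 2 and 16 without untreated replicate 1. Of 31 E2F targets and DNA replication genes, 8 fell, 23 when adjusted over the list alone, with a median of -1.14. Among them were E2F2, a transcription factor of the cell cycle (-2.95, SE 0.48), and the replicative helicase subunits MCM6 (-1.82, SE 0.28), MCM2 (-1.57, SE 0.27) and MCM3 (-1.48, SE 0.24). That list was below the other genes as well (adjusted p = 1.19e-22, and adjusted p = 0.167 with an estimated correlation). None of its members passed without zeocin replicate 1 or untreated replicate 2, 2 passed without zeocin replicate 2, and 13 to 17 passed when a library of the infection experiment was left out. Of 28 genes of double-strand break sensing and repair, FANCD2 alone passed, falling by 1.11 (SE 0.24, adjusted p = 0.0492), while adjusted over the list alone 10 were lower and 1 higher. No repair gene passed without untreated replicate 2 or zeocin replicate 1, and 3 to 6 passed without a library of the infection experiment. The median was -0.40 (camera adjusted p = 4.39e-05, and adjusted p = 0.600 with an estimated correlation).

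Targets of p53 rose with zeocin: 6 of 29 tested members passed, 13 when adjusted over the list alone, none fell, and 26 of 29 lay above 0, with a median of 0.72. The list was above the other genes with the preset correlation (adjusted p = 8.50e-18) and with an estimated correlation (adjusted p = 0.0477), the sole list call that held under both in any comparison. The members with the smallest p were PLK3, a stress-responsive kinase (1.67, SE 0.32), CDKN1A, ACER2, an alkaline ceramidase (1.92, SE 0.38), and RRM2B, a ribonucleotide reductase subunit (1.03, SE 0.21). MDM2, a ubiquitin ligase, rose from 391.6 ± 70.4 to 877.6 ± 90.8 CPM (1.16, SE 0.24, adjusted p = 0.0363). The kinases of the damage checkpoint ATM (0.06, SE 0.23), CHEK1 (-0.52, SE 0.30) and CHEK2 (-0.55, SE 0.29) did not pass, with adjusted p of 0.972, 0.604 and 0.538. Without untreated replicate 1, 1 p53 target passed, and 0 passed without untreated replicate 2, zeocin replicate 1 or zeocin replicate 2. Without mock replicate 1 or mock replicate 2, 9 passed.

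**Figure D3:**
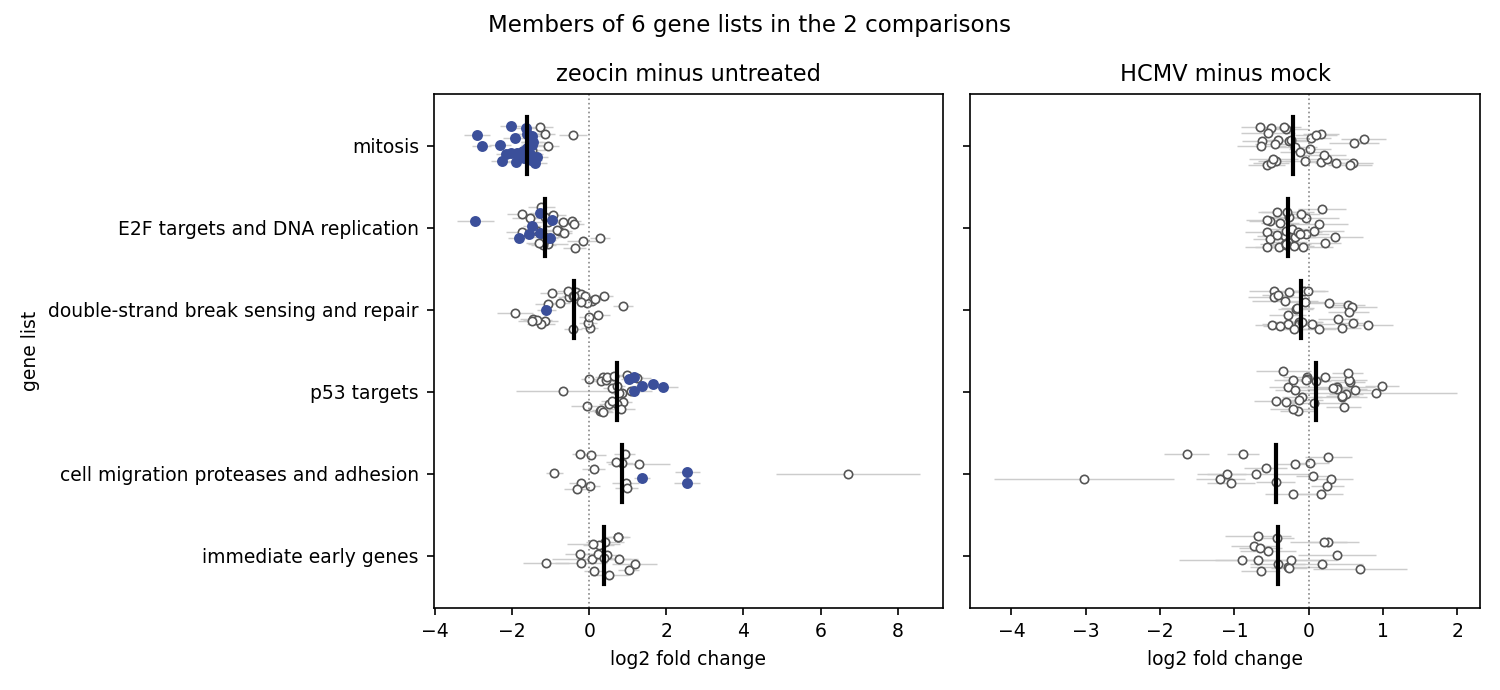
Log2 fold change (horizontal axes, which differ in scale) of each tested member of 6 gene lists with zeocin (left) and with HCMV (right). Filled points passed an adjusted p of 0.05 (edgeR), open points did not, grey lines are SE and black bars medians. The mitosis median lies at -1.60 with zeocin and at -0.21 with HCMV, where no point is filled.

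Other groups had members that rose with zeocin. Of 17 tested genes of cell migration, PLAU, the urokinase plasminogen activator (2.54, SE 0.32), ITGA2, the integrin alpha 2 chain (2.54, SE 0.34), and CD44, a hyaluronan receptor (1.37, SE 0.22), passed, 9 rose and 1 fell when adjusted over the list alone, and the median was 0.85 (camera adjusted p = 1.19e-05, and adjusted p = 0.0961 with an estimated correlation). Of 12 proteins linked to HCMV entry, the integrin chains ITGA2 and ITGA6 (1.16, SE 0.25) passed, 4 when adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.000212, and adjusted p = 0.105 with an estimated correlation). Of 20 genes of the unfolded protein and integrated stress response, HYOU1, a chaperone of the endoplasmic reticulum, rose (1.06, SE 0.20), 2 when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.000153, and adjusted p = 0.410 with an estimated correlation). Without zeocin replicate 1 none of the migration, entry or stress response genes passed. Without untreated replicate 1 or 2 there passed 2 migration genes, 1 entry protein and 0 stress response genes, without zeocin replicate 2 there passed 1 entry protein and 0 stress response genes, and 5 migration genes rose and 1 fell without mock replicate 1 or 2. Immediate early genes had a median of 0.38 with 0 of 17 called and 1 adjusted over the list alone (camera adjusted p = 0.00568, and adjusted p = 0.668 with an estimated correlation). Matrix and contractile genes had a median of 0.23 with 0 of 22 called and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0254, and adjusted p = 0.752 with an estimated correlation), and their median was -0.13 without untreated replicate 2 and -0.14 without zeocin replicate 1. Called matrix genes numbered 3 higher and 1 lower without mock replicate 1 or 2, 2 higher and 1 lower without HCMV replicate 1 or 2, and 1 higher without untreated replicate 1 or zeocin replicate 2. There was 1 immediate early gene called higher without mock replicate 1, mock replicate 2 or HCMV replicate 2. The matrix call was also lost with the stricter filter (adjusted p = 0.0588) and with the experiment fitted alone (0.0945). Without untreated replicate 1 the immediate early and stress response lists were not called (adjusted p = 0.0746 for both).

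Lists of other functions and cell types gave no call by camera with zeocin. IFI44L, an interferon-stimulated gene, rose from 3.8 ± 1.3 to 21.1 ± 1.5 CPM (2.47, SE 0.32), and none of the other 20 tested interferon-stimulated genes passed (median -0.13, adjusted p = 0.895). Of 12 epithelial genes, CLDN1, a tight junction protein, rose (1.03, SE 0.22) and ELF3, an epithelial transcription factor, fell (-2.62, SE 0.41), with a median of 0.18 and adjusted p = 0.677. PDGFRB, a marker in the fibroblast list, fell (-1.48, SE 0.30), the only one called of 5 tested (median 0.11, adjusted p = 0.895). No member passed among NF-kB targets and cytokines (median -0.02, adjusted p = 0.895), heat shock genes (0.00, adjusted p = 0.895), sterol and fatty acid synthesis (0.03, adjusted p = 0.249), glycolysis (-0.11, adjusted p = 0.677), retinal pigment epithelium markers (-0.43, adjusted p = 0.150), MHC class I presentation (0.07, adjusted p = 0.150) and endothelial markers (-0.21, adjusted p = 0.895). Adjusted over the list alone, 1 of the NF-kB list, 1 of the interferon list, and 1 gene in each direction of the epithelial and fibroblast lists passed. Only 2 of 11 leukocyte markers were expressed enough to be tested, and neither passed in any comparison. IFI44L did not pass without zeocin replicate 1. CLDN1 did not pass with any 1 of the 4 libraries of the zeocin experiment left out, and ELF3 and PDGFRB passed only where that library was untreated replicate 2. The MHC class I list was called by camera with the experiment fitted alone (adjusted p = 0.0400) and with the replicate block (adjusted p = 0.0139). Of the lists that mark RNA quality, the 13 mitochondrially encoded mRNAs were all above 0 with 0 called (median 0.32, camera adjusted p = 0.000482, and adjusted p = 0.649 with an estimated correlation). That call was lost without untreated replicate 1 (adjusted p = 0.175) and without zeocin replicate 2 (adjusted p = 0.109). The ribosomal protein genes had a median of 0.04 (adjusted p = 0.429). Camera called the sterol list without untreated replicate 2 (median 0.29, adjusted p = 0.00242). It called the NF-kB list (median 0.27, adjusted p = 0.0448) and the pigment epithelium markers (median -0.91, adjusted p = 0.0287) without zeocin replicate 2.

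Outside these lists, the largest rises with zeocin after PLAT were IL33, an alarmin cytokine (3.25, SE 0.37), CNIH3 (3.06, SE 0.55), BLID (2.64, SE 0.39), FLG2, a filaggrin-family protein (2.32, SE 0.28), IL13RA2, the decoy receptor of interleukin 13 (2.27, SE 0.36), and COL4A6, a type IV collagen chain (2.26, SE 0.36). The largest falls included CDKN2C, the cyclin-dependent kinase inhibitor p18 (-3.06, SE 0.38), PIF1, a DNA helicase (-2.62, SE 0.49), and 4 histone genes of the replication-dependent clusters, H2BC3 (-3.30, SE 0.45), H3C1 (-3.20, SE 0.58), HIST1H3C (-2.78, SE 0.47) and H3C10 (-2.67, SE 0.53). Histone genes have near-identical copies, and their single values are uncertain. DESeq2 called 532 genes (242 higher and 290 lower), among them 215 of the 218. The count rested on single libraries: 5 genes passed without zeocin replicate 1, 127 without zeocin replicate 2, 103 without untreated replicate 1 and 49 without untreated replicate 2, while 407 and 427 passed without mock replicate 1 and 2. PLAT, IL33 and KIF20A passed under each of 18 alternatives. Scaling by library size alone split the calls into 75 higher and 166 lower.

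**Figure D4:**
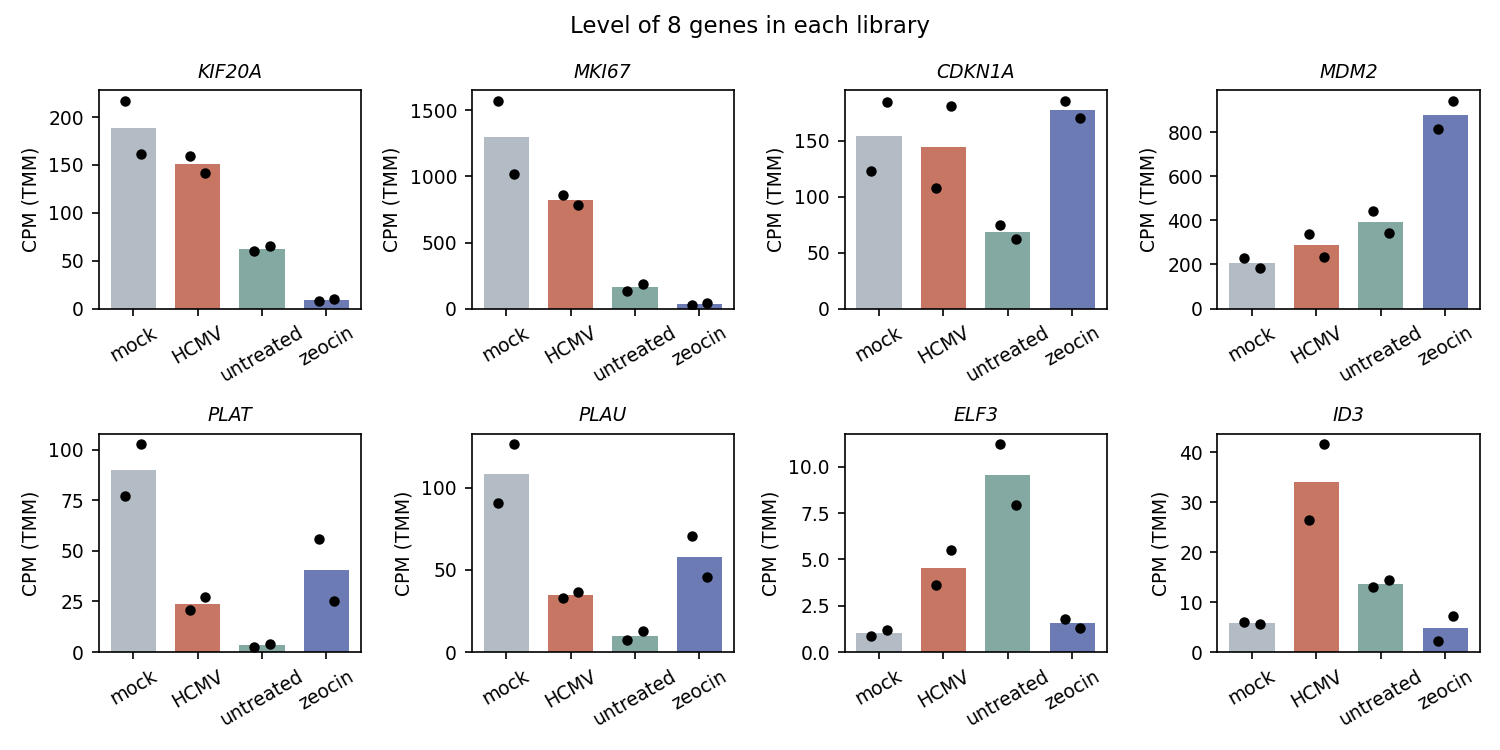
Level of 8 named genes in CPM of TMM-scaled libraries (vertical axes from 0, which differ in scale) in the 4 groups. Bars are means and points single libraries. KIF20A is lowest with zeocin at 9.0 CPM, and PLAT is lower with HCMV than in mock cells and higher with zeocin than in untreated cells.

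With HCMV, no host gene passed the threshold in edgeR. Of 21258 genes, 0 were called and 1689 had an unadjusted p under 0.05 (1088 higher and 601 lower), with a lowest adjusted p of 0.145. DESeq2 called 125 genes, 90 higher and 35 lower, and the values that follow passed in DESeq2 but not in edgeR. ID3, ID2 and ID4, inhibitors of differentiation that block helix-loop-helix transcription factors, were higher with HCMV: ID3 stood at 5.8 ± 0.4 CPM in mock and 34.0 ± 10.7 CPM in infected cells (edgeR log2 fold change 2.55, SE 0.43, adjusted p = 0.145; DESeq2 adjusted p = 3.55e-06), ID2 at 2.8 ± 0.8 and 14.4 ± 0.4 CPM (2.36, SE 0.38) and ID4 at 2.6 ± 1.1 and 9.6 ± 1.2 CPM (1.91, SE 0.39). PLAT stood at 89.8 ± 18.2 CPM in mock and 24.0 ± 4.3 CPM in infected cells (-1.90, SE 0.35, edgeR adjusted p = 0.162, DESeq2 adjusted p = 0.00021).

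The other 7 largest rises by DESeq2 were TSPAN2, a tetraspanin (edgeR log2 fold change 1.79, SE 0.41), NECAB1 (1.66, SE 0.44), NEBL, the actin-binding nebulette (1.64, SE 0.25), GASK1B (1.62, SE 0.32), TLCD4 (1.55, SE 0.30), RN7SKP71 (2.02, SE 0.53) and RN7SKP203 (1.74, SE 0.45). RN7SKP71 and RN7SKP203 are 7SK pseudogenes by name that the annotation did not mark as such, and their values are uncertain. RN7SKP71 stood at 40.4 CPM in HCMV replicate 1 and 8.59 CPM in HCMV replicate 2, and without HCMV replicate 1 the values of RN7SKP71 and RN7SKP203 were 0.59 and 0.56. NECAB1 was at 1.00 without mock replicate 1 and 2.78 without mock replicate 2. The largest drops beside PLAT were EPHB1, an ephrin receptor (-2.12, SE 0.40), the chemokine receptor CXCR4 (-1.82, SE 0.33), DUSP6, a phosphatase that acts on ERK (-1.81, SE 0.40), IL33 (-1.69, SE 0.35), the neuropilin NRP1 (-1.68, SE 0.34), PLAU (-1.64, SE 0.30), STX1A (-1.61, SE 0.43, and -0.78 without mock replicate 2), CDCP1 (-1.58, SE 0.27) and GPAT3 (-1.52, SE 0.41). In simulated data 29 of 160 DESeq2 calls in this comparison were false, against 9 of 120 in edgeR. With a replicate block edgeR called 416 genes, but that fit takes same-numbered libraries as pairs, which no label does. The edgeR count of 0 became 146 without HCMV replicate 2, 44 without mock replicate 2, 12 without mock replicate 1, 3 without untreated replicate 2, 1 without either zeocin replicate, and 163 without a filter on low counts.

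No member of any list was called by edgeR with HCMV when all libraries were used. Without mock replicate 1, 2 migration genes were called lower, and without HCMV replicate 2, 1 p53 target and 2 sterol genes were called higher and 1 glycolysis gene lower. Glycolysis genes had a median log2 fold change of -0.39 with 17 of 19 below 0, as for PKM at -0.60 (SE 0.22) and ENO1 at -0.58 (SE 0.21), and camera placed them below the other genes (adjusted p = 7.58e-07, and adjusted p = 0.490 with an estimated correlation). The same direction was found for cell migration genes (median -0.45, adjusted p = 8.75e-05, and adjusted p = 0.394 with an estimated correlation), of which 5 passed adjusted over the list alone, for E2F targets (-0.27, adjusted p = 0.000659, and adjusted p = 0.748 with an estimated correlation), for unfolded protein response genes (-0.33, adjusted p = 0.00593, and adjusted p = 0.579 with an estimated correlation) and for mitosis genes (-0.21, adjusted p = 0.0143, and adjusted p = 0.787 with an estimated correlation). Both RNA-quality lists moved with them: all 24 ribosomal protein genes lay below 0 (median -0.31, adjusted p = 6.27e-07, and adjusted p = 0.394 with an estimated correlation), as did 12 of 13 mitochondrially encoded mRNAs (median -0.40, adjusted p = 1.04e-05, and adjusted p = 0.579 with an estimated correlation). Across genes the HCMV fold change fell with the GC content of the gene (Spearman correlation -0.28, against -0.059 for the zeocin fold change). Whether this trend accounts for the shifts of these lists was not tested. Targets of p53 had a median of 0.10, above the other genes (adjusted p = 0.0182, and adjusted p = 0.490 with an estimated correlation), and the cyclin CCNG1 (0.99, SE 0.23) was the 1 member that passed adjusted over the list alone. Without mock replicate 1 the mitochondrial mRNAs (adjusted p = 0.395), the p53 targets (adjusted p = 0.121) and the mitosis genes (median 0.10, adjusted p = 0.901) were no longer called, and without HCMV replicate 2 the p53 targets (median -0.20, adjusted p = 0.457) and the mitosis genes (median 0.01, adjusted p = 0.981) were not. The p53 call was also lost with the experiment fitted alone (adjusted p = 0.0807) and without a filter on low counts (0.0548), and the mitosis call with DESeq2 (0.119), the experiment fitted alone (0.107) and the stricter filter (0.0626).

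The remaining lists gave no camera call with HCMV. Interferon-stimulated genes had a median of 0.20 (adjusted p = 0.556) and NF-kB targets and cytokines of -0.03 (adjusted p = 0.782). The panel of damage genes did not pass, with CDKN1A at -0.09 (SE 0.27), MDM2 at 0.47 (SE 0.24), ATM at 0.53 (SE 0.23), CHEK1 at 0.05 (SE 0.30) and CHEK2 at -0.06 (SE 0.29), and genes of double-strand break sensing and repair had a median of -0.11 (adjusted p = 0.556). Medians were -0.42 for immediate early genes (adjusted p = 0.119), 0.09 for heat shock genes (adjusted p = 0.935), 0.15 for sterol and fatty acid synthesis (adjusted p = 0.0537), 0.00 for matrix and contractile genes (adjusted p = 0.904), -0.08 for epithelial genes (adjusted p = 0.653), 0.10 for retinal pigment epithelium markers (adjusted p = 0.653), -0.09 for MHC class I presentation (adjusted p = 0.556) and -0.19 for the entry proteins (adjusted p = 0.0684). Markers of fibroblasts (0.60, adjusted p = 0.556) and endothelium (-0.59, adjusted p = 0.782) gave no call either. Camera called the sterol list without mock replicate 2 (adjusted p = 0.00623) and HCMV replicate 1 (0.00455), the repair list without the same libraries (0.00878 and 0.00599), and the immediate early list without mock replicate 1 (1.04e-05) and HCMV replicate 2 (0.00171). The sterol list was called as well with RLE scaling (0.0441), library size alone (0.0174), the stricter filter (0.0440) and DESeq2 (0.0363). The immediate early list was called with DESeq2 (0.0139) and with the replicate block (0.00205). Without a filter on low counts the immediate early (0.0238), repair (0.0438) and entry protein lists (0.00460) were called. Camera also called the entry proteins without mock replicate 2 (0.0350), HCMV replicate 1 (0.00661), untreated replicate 1 (0.0465) and untreated replicate 2 (0.0448). Adjusted over the list alone, 3 sterol and fatty acid genes, 1 epithelial gene and 1 fibroblast marker were higher, and 1 NF-kB target and 1 entry protein lower. The median differed in sign from the direction of the test for the epithelial and matrix lists here and for the interferon, NF-kB, heat shock and fibroblast lists with zeocin. For the endothelial list the mean, 0.16, lay above 0 and the median and test below. Scaling by library size alone moved the median of all genes by 0.11 on the log2 scale for HCMV, by -0.07 for zeocin and by 0.18 for the difference of effects.

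The responses to HCMV and zeocin differed for part of the genes. The test of the difference of effects, HCMV against mock minus zeocin against untreated, called 167 genes, 64 with a higher and 103 with a lower HCMV effect. PLAT had the lowest difference (-5.49, SE 0.52, adjusted p = 0.00139), followed by XDH, xanthine dehydrogenase (-5.06, SE 0.72), IL33 (-4.94, SE 0.50), TMEM158 (-4.37, SE 0.77) and PLAU (-4.18, SE 0.44). The highest were the long noncoding RNA AC016717.2 (5.97, SE 0.77), EDN2, endothelin 2 (5.05, SE 0.78), the transcription factors ATOH8 (4.86, SE 0.85) and ELF3 (4.79, SE 0.58), and ID3 (4.09, SE 0.61). Some of these values rest on low or uneven counts. AC016717.2 had 2 and 4 counts in the mock libraries, XDH 10 and 6 in untreated, and ATOH8 6 and 46 in zeocin. EDN2 had 22 and 10 counts in mock, and 478 and 104 in untreated. With library size alone, the split of the calls was 97 higher and 75 lower.

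By list, 7 mitosis genes and 1 E2F target differed, with HCMV above zeocin, as did ELF3 of the epithelial list and PDGFRB of the fibroblast list (2.39, SE 0.42). In the other direction differed 4 migration genes, among them the entry protein ITGA2 (-3.73, SE 0.47), and HYOU1 (-1.40, SE 0.27), IFI44L (-3.46, SE 0.45), the cytokine IL1B (-4.28, SE 0.74) and the matrix protein TNC (-3.75, SE 0.71). The 7 mitosis genes became 1 without zeocin replicate 1, 3 without untreated replicate 2, 4 without untreated replicate 1 or HCMV replicate 1, 10 without zeocin replicate 2 and 15 to 17 without another infection library, and no E2F target passed without untreated replicate 2 or zeocin replicate 1. HYOU1 did not pass without HCMV replicate 1 or any 1 library of the zeocin experiment. Neither IL1B nor TNC passed without HCMV replicate 1, untreated replicate 1 or zeocin replicate 1, nor TNC without untreated replicate 2. PDGFRB did not pass without untreated replicate 1 or either zeocin replicate. Camera called 11 lists in this comparison, whose values stand in the closing section, and none of these calls held with an estimated correlation (lowest adjusted p = 0.147). Median, mean and test differed in sign for the heat shock (0.07, mean 0.00, test down), epithelial (-0.17, mean 0.23) and endothelial lists (-0.45, mean 0.36). Across genes the 2 sets of fold changes were weakly and negatively correlated (Pearson -0.0608 over 21258 genes, Spearman -0.0786, and -0.138 and -0.120 over 9215 genes with a mean of at least 10 CPM, where Pearson was -0.0819 without HCMV replicate 2 and -0.175 without HCMV replicate 1), and genes are not independent replicates. No gene was called in both comparisons by edgeR, since HCMV had 0 calls. Among DESeq2 calls, 28 of the 35 genes lower with HCMV were higher with zeocin, against 0.398 by chance (one-sided Fisher's exact test over genes, adjusted p = 1.90e-48), and 13 of the 90 genes higher with HCMV were lower with zeocin, against 1.23 by chance (adjusted p = 5.57e-10). None was higher in both or lower in both, where chance would give 1.02 and 0.477. These chance values count all 21258 genes. DESeq2 gave no adjusted p for 6595 genes with HCMV and 4122 with zeocin, which were counted as not called. The chance values are therefore too low, and the Fisher p-values overstate the evidence. The count of 167 was 41 without zeocin replicate 1, 44 without untreated replicate 1 and 72 without HCMV replicate 1, and 306, 322 and 285 without mock replicate 1, mock replicate 2 and HCMV replicate 2, and DESeq2 called 508.

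**Figure D5:**
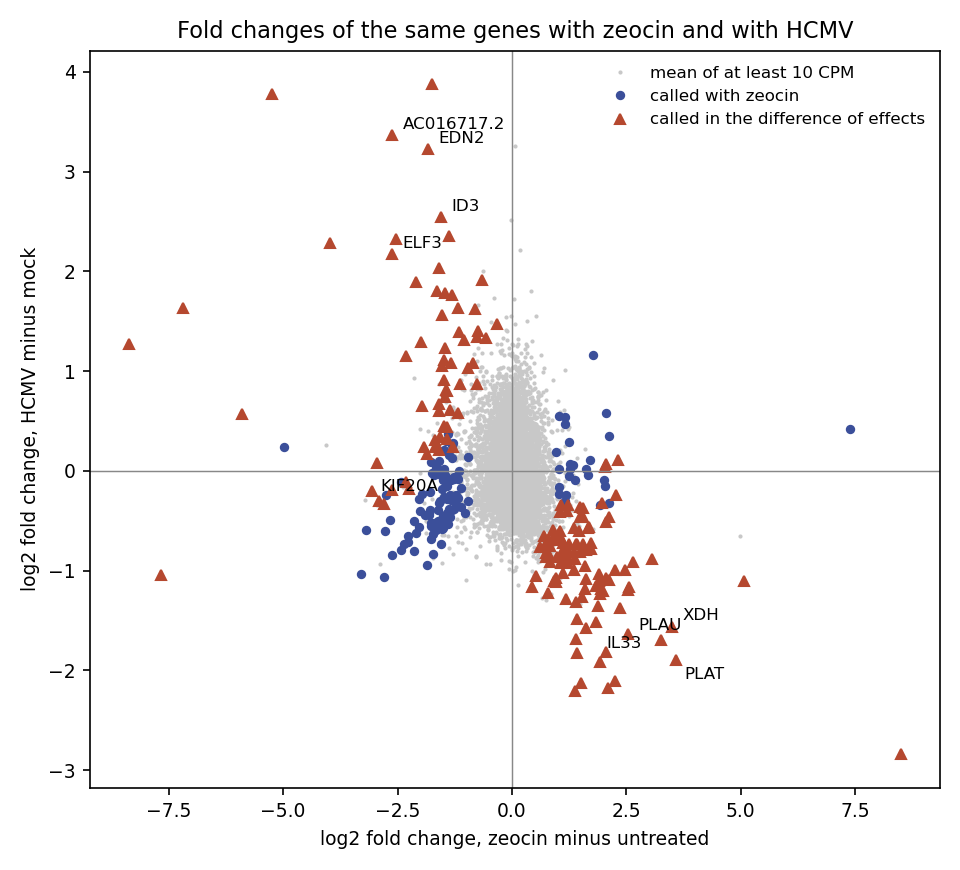
Log2 fold change of each gene with zeocin (horizontal axis) and with HCMV (vertical axis). Grey points are genes with a mean of at least 10 CPM, blue circles genes called with zeocin alone and red triangles the 167 genes called in the difference of effects.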

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

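The tests of a replicate number shared between mock and HCMV libraries and of RNA without a poly(A) tail, and the fit with limma voom and library weights, were chosen only after the results they bear on were seen. The results below drew attention because the effect of HCMV and the effect of zeocin, each against its own control, differed by the edgeR test of that difference.

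In all, 167 genes differed between the effects. The named genes were AC016717.2 (5.97), EDN2 (5.05), ATOH8 (4.86), ELF3 (4.79) and ID3 (4.09), where the HCMV effect was higher on the log2 scale, and PLAT (-5.49), XDH (-5.06), IL33 (-4.94), TMEM158 (-4.37) and PLAU (-4.18), where it was lower. The values of AC016717.2, EDN2, ATOH8 and XDH rest in part on the low or uneven counts given above. TMEM158 was not called without HCMV replicate 1 (adjusted p = 0.0765) or untreated replicate 1 (0.0921), and its value was -2.71 without mock replicate 2. ATOH8 was not called without untreated replicate 1 (0.0564), nor EDN2 with limma voom and library weights (0.0993).

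By camera with the preset correlation, the HCMV effect lay above the zeocin effect for mitosis genes (median difference 1.63, adjusted p = 2.69e-30), E2F targets (0.83, adjusted p = 2.91e-09) and genes of double-strand break repair (0.53, adjusted p = 0.00567). It lay below for p53 targets (-0.62, adjusted p = 2.85e-06), cell migration genes (-1.15, adjusted p = 3.23e-07), entry proteins (-0.79, adjusted p = 0.000205), immediate early genes (-0.74, adjusted p = 0.00172), the unfolded protein response (-0.64, adjusted p = 9.34e-06) and glycolysis (-0.29, adjusted p = 0.00382). The RNA-quality lists lay below as well, at -0.70 for mitochondrially encoded mRNAs (adjusted p = 1.90e-07) and -0.31 for ribosomal protein genes (adjusted p = 0.000103). None of these calls held with an estimated correlation, where the lowest adjusted p was 0.147. Without mock replicate 2 the repair (adjusted p = 0.158), immediate early (0.130) and glycolysis (0.0665) lists were not called, and the repair list was not called without HCMV replicate 1 (0.0863), untreated replicate 2 (0.231) or zeocin replicate 1 (0.0752), nor glycolysis without HCMV replicate 1 (0.103) or untreated replicate 1 (0.0546). Other lists were called with 1 library left out. The median difference was -0.62 for matrix genes without untreated replicate 1 and -0.47 without zeocin replicate 2. For pigment epithelium markers it was 0.50 without mock replicate 1 and 0.78 without zeocin replicate 2. It was -0.26 for MHC class I presentation without HCMV replicate 2 and -0.28 for NF-kB targets without zeocin replicate 2. Camera called the matrix and MHC class I lists as well without a filter on low counts (0.0376 and 0.0187) and with the replicate block (0.0389 and 0.0102).

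The first pattern is that effects were opposed for genes raised by zeocin: the 89 genes called higher with zeocin had a median log2 fold change of -0.57 with HCMV, and 71 of them lay below 0, against a range of -0.13 to 0.06 for the middle 95% of 10000 random lists matched on expression. The 129 genes called lower with zeocin were not opposed: their HCMV median, -0.19, lay on the same side as with zeocin and below the random range of -0.12 to 0.03, though it was 0.00 without mock replicate 1. A trend with gene length or GC is argued against, since the first median was -0.57 (-0.571) after both trends were removed. A single library of the infection experiment is argued against too, since the median stayed between -0.651 and -0.509 whichever of the 4 was left out. The 89 genes were called with all libraries. Sets called without 1 library of the zeocin experiment were not tested for the pattern. The random lists also lack the correlation between co-regulated genes, so their ranges are too narrow. A response of the cells to infection and to DNA damage stays open as a hypothesis, as does an unmeasured difference in the state of the cells between the experiments, whose controls lay far apart.

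The second pattern is that edgeR called no host gene with HCMV although the HCMV libraries held viral RNA, at 0.280 and 0.442% of counts. The share of cells that were infected was not measured here, and whether host changes were limited to a part of the cells was not tested. Whether the shallow HCMV library was the cause was not decided. The prediction that genes would pass without HCMV replicate 1 was not met. That fit leaves a single HCMV library, so it cannot tell depth from the lost replicate. Thinning the other 3 libraries of that experiment to the depth of HCMV replicate 1 gave 1722 genes at an unadjusted p under 0.05, against 1689. Such a small change was predicted for that cause, but would also be seen if depth did not matter. Spread shared by libraries of the same number is a candidate explanation, since mock and HCMV libraries of 1 number deviated together (correlation 0.361) and a replicate block called 416 genes. The block also raised the zeocin count from 218 to 1051, where such libraries hardly deviated together (0.0354). A rise in calls alone therefore does not show shared spread, and 2 pairs cannot establish that the numbers mark a shared day or culture. Host changes near 1 on the log2 scale stay open. In simulated data of this size, with 200 genes changed by design, edgeR made 120 calls and recovered 86% of changes of 2 and 17% of changes of 1. How many genes changed was set in advance there and is unknown in the real data. The simulation therefore cannot tell whether sample size accounts for the 0, although ID3 was estimated at 2.55.

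The third pattern is that the control libraries of the experiments lay apart, with 8675 genes called. Across 13807 protein-coding genes the mock minus untreated fold change rose with GC (Spearman correlation 0.679), from a median of -0.97 in the fifth of genes lowest in GC to 1.37 in the highest, which a difference in library preparation or sequencing between the experiments could give. The trend with gene length was weaker (-0.273, and -0.129 once GC was held fixed), short of the -0.3 set beforehand for length as the cause. More RNA without a poly(A) tail in the zeocin experiment, where SNORD3A, which has no such tail, was abundant, predicted replication-dependent histone genes lower in mock. Instead all 50 tested were higher in mock (median 3.60), and so was 7SK. The GC trend and the state of the cells were not separated from this shift, so the test cannot decide. Different culture states of the cells were not tested.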

How the results depend on the processing

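The fits with limma voom weights, with human and viral rows together and with DESeq2 on each experiment alone were chosen after the counts of calls were seen; the others were planned. For HCMV minus mock the count of 0 genes became 163 without a filter on low counts, 125 with DESeq2, 31 with DESeq2 on the experiment alone and 35 with viral rows included, and 0 to 146 when 1 library was left out (146 without HCMV replicate 2, 44 without mock replicate 2, 12 without mock replicate 1). It was 0 with RLE scaling, library size alone, the stricter filter, voom weights and a fit of the experiment alone. For zeocin minus untreated the count of 218 became 558 without the filter, 532 with DESeq2, 609 with the experiment fitted alone, 999 with DESeq2 on it alone and 370 with voom weights, and ran from 5 (without zeocin replicate 1) to 427 (without mock replicate 2). For the difference of effects the count of 167 became 557 without the filter and 508 with DESeq2, and ran from 41 to 322 over left-out libraries. An arm left with 1 library is assumed to vary like the other groups, and fewer libraries enter those fits; otherwise the cause was not tested. Genes called in both comparisons in opposite directions numbered 0 by edgeR and 41 by DESeq2, and the correlation of the fold changes went from -0.0608 to -0.138 over genes of at least 10 CPM.

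With the replicate block, which treats same-numbered libraries as paired, the counts were 416 for HCMV, 1051 for zeocin and 1182 for the difference. Libraries of the same number deviated together for mock and HCMV (correlation 0.361) and hardly for untreated and zeocin (0.0354), and the numbers were not taken as pairs.

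The direction of the camera test was reversed for 1 list called with all libraries, in 2 settings: matrix and contractile genes with zeocin had medians from -0.142 without zeocin replicate 1 and -0.132 without untreated replicate 2 to 0.562 without untreated replicate 1, against 0.232; the cause was not tested. The median alone changed sign, and the call was lost, for HCMV p53 targets (0.0977) at -0.204 without HCMV replicate 2, and for HCMV mitosis genes (-0.212) at 0.0993 without mock replicate 1 and 0.0112 without HCMV replicate 2. With the estimated correlation, 8 list calls for HCMV, 9 for zeocin and 11 for the difference were lost. No named gene that was called changed direction under any alternative run. Depth limits genes of low counts most in HCMV replicate 1, where 3 counts make 3.27e-05% of the library.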

Other observations

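The tests of MAPK output and of BMP and SMAD targets were written before the medians of their lists were seen. The descriptions in the next paragraph and the interval for the BMP and SMAD list were chosen after the values were seen.

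Some genes with opposed effects stood at different levels in the controls of the 2 experiments. PLAT was at 89.8 ± 18.2 CPM in mock and 3.4 ± 1.1 CPM in untreated cells, with HCMV (24.0 ± 4.3 CPM) and zeocin (40.4 ± 21.6 CPM) between. PLAU likewise was at 108.4 ± 25.3 CPM in mock, 34.7 ± 2.9 CPM with HCMV, 58.0 ± 17.7 CPM with zeocin and 10.0 ± 3.9 CPM in untreated cells. NEBL ran the other way, from 10.3 ± 2.4 CPM in mock through 32.2 ± 8.1 CPM with HCMV and 63.0 ± 0.7 CPM with zeocin to 142.6 ± 13.8 CPM in untreated cells. Levels in different experiments carry the difference in RNA composition described above.

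Genes induced by ERK/MAPK signalling are a candidate source of the opposed effects. A list of 22 MAPK output genes had a median difference of effects of -1.02, at percentile 0 of 10000 random lists matched on expression (MAPK output lower with HCMV and higher with zeocin was the prediction, and -0.29 the lower bound of the middle 95% of random lists). The median was -0.52 with HCMV, where 19 of 22 lay below 0, and 0.56 with zeocin, where 17 of 22 lay above 0. CCND1, cyclin D1 (-2.30, SE 0.33), HMGA2 (-2.51, SE 0.44) and the feedback inhibitor SPRY2 (-2.02, SE 0.36) passed the test of the difference, and 5 of the 22 stood in lists tested earlier, LIF among the named genes, without which the median was -1.21, again at percentile 0. CCND1, HMGA2 and ELK3 were also among the genes called higher with zeocin that define the opposed pattern, so the list and the pattern share genes. Random lists do not hold the correlation between co-regulated genes, so the percentile overstates the evidence, and these data suggest the link only as a hypothesis.

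A list of 15 BMP and SMAD target genes, tested because ID2, ID3, ID4 and ATOH8 had positive differences, did not reach the predicted value. Its median difference was -0.08, at percentile 31.1 of random lists, and the prediction was a median above 0.47, the upper bound of their middle 95%. The zeocin median, predicted to be low, was 0.28, at percentile 97.9, with 10 of 15 above 0, and the HCMV median was 0.25, at percentile 96.3. Members went both ways, 7 above and 8 below 0, and the interval for the median difference from its order statistics was -0.46 to 1.95, which contains 0.47, so the hypothesis stays open without support. Resampling the members was tried first and replaced because its upper end was 1.03 or 1.95 depending on the seed. SMAD6 (2.25, SE 0.40) and SMAD9 (2.60, SE 0.42) passed the test of the difference, both with HCMV above zeocin, and members such as NOG (-2.74, SE 0.86) lay on the other side without passing.

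Replication-dependent histone genes, a group outside the fixed lists that was chosen after values were seen, were lower with zeocin for 11 of 50 tested genes, against 129 of all 21258, and higher for 0, with a median of -1.27. The 11 became 0 without zeocin replicate 1, 1 without untreated replicate 2, and 16 to 22 without a library of the infection experiment, with medians from -1.88 to -1.04. No test of the group as a set was run. Its median with HCMV was -0.73, from -1.16 without HCMV replicate 2 to -0.37 without HCMV replicate 1, where edgeR called none (of all 21258 genes, 1689 had an unadjusted p under 0.05 and DESeq2 called 125).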
